A study of Mus musculus with 3 samples.

How the data were processed

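Total RNA was prepared with a stranded Illumina library kit, per the labels' protocols, and the submitters' processing notes name cutadapt, HTSeq 0.6.0 and the genome build mm10. The series text speaks of microarrays, whereas its labels describe sequencing libraries. The aligner and the method of normalization are not given in the sources used here. The authors deposited 2 tables, 1 named for raw and 1 for normalized gene counts, with genes in rows and 3 value columns each.

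The tables hold 6 value columns in all, and none of the 6 was used here. Each column name was searched, with punctuation and letter case ignored, in the title, description, source name and characteristics of each sample, and none was found. The columns were therefore not assigned to a stage, no depth per library is given, and no test, fold change or gene list score was computed. The comparisons, the rule for named genes and the gene lists had been fixed before the data were examined. The named-gene rule ranks genes by their difference between libraries and was not applied. Genes named in the results were chosen from the lists as examples of their coverage.

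The column of gene symbols was compared between the tables and matched, by exact spelling, to the symbols of GENCODE M21 and to the 51 gene lists. As an alternative, symbols were matched to RefSeq for GRCm38.p6, to either annotation, or to the lists with letter case ignored.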

Results

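RNA was sequenced from tumor cells at 3 stages, from uncastrated mice to castration-resistant regrowth, with 1 library per stage and 3 libraries in all. The tumors were grown under the skin of FVB mice from Myc-CaP cells, a mouse prostate cancer line derived from a tumor of a MYC-transgenic mouse. A mouse age of 6 weeks is recorded for every stage. The recorded days differ between the stages (0 for PPC, 10 for S-PC and 30 for CRPC). The recorded age therefore need not be the age at collection, and the stages cannot be taken as matched for age. The primary stage (PPC) was taken from uncastrated mice once tumors had reached 500 mm3, and its label gives day 0. The shrunken stage (S-PC) was taken 10 days after castration, which was done at a tumor volume of about 500 mm3. The labels used here give no volume at collection for that stage. The castration-resistant stage (CRPC) was taken after tumors had regrown to 500 mm3 following castration, and its label gives day 30. The design implies 3 comparisons: shrunken against primary, castration-resistant against primary, and castration-resistant against shrunken tumor cells.

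None of these comparisons was made here, and no expression level is reported for any stage. The value columns of the gene tables carry running numbers that appear in no label of the samples. Of the 6 value columns, 0 could be assigned to 1 sample by name. Assigning them by their order, or by the level of a gene that castration is known to affect, would have fixed the direction of each comparison by assumption. With 1 library per stage, no replicate could have shown such an assignment to be wrong.

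Each of the 2 tables listed the same 37411 gene symbols in the same order, with 0 repeated symbols. Of these symbols, 36174 (96.7%) were found in the GENCODE M21 annotation of the mouse genome build GRCm38. Among 1398 distinct symbols in 51 gene lists fixed before the data were examined, 1366 had a row. Some lists held more than 1 name for the same gene, so a symbol without a row is not always a gene without one. Of 48 symbols listed for the androgen response, 47 had a row, among them Fkbp5, which androgens induce, and Pbsn, which encodes the prostate secretory protein probasin. The symbol without a row in that list, Probasin, is another name of Pbsn. All 27 symbols for steroid receptors and their cofactors had a row, including Nr3c1, the glucocorticoid receptor. Of 31 symbols for steroid synthesis, 30 had a row, and Sts, which encodes steroid sulfatase, had none. The lists for luminal epithelial (30 symbols), basal epithelial (20 symbols) and neuroendocrine cells (28 symbols) were covered in full, as were those for DNA replication (36 symbols) and mitosis (40 symbols). Among markers of other cell types, all 29 symbols for macrophages and monocytes, 26 for fibroblasts and 22 for endothelium had a row. The red blood cell list had rows for 9 of 12 symbols, without Hbb-b1, Hbb-b2 and Ahsp. The beta-globin symbols Hbb-bs and Hbb-bt of that list had rows. Coverage by symbol was also incomplete for the nuclear genes of oxidative phosphorylation (48 of 54 symbols) and for mitochondrially encoded genes (15 of 28 symbols). The mitochondrial list held both mouse-style and upper-case names, and only upper-case names had no row. In the nuclear list, Atp5f1a, Atp5f1b, Atp5f1c, Atp5f1d, Atp5po and Atp5pb had no row. Other names of these genes except Atp5pb were in the same list and had rows (Atp5a1, Atp5b, Atp5c1, Atp5d and Atp5o). A row shows that a gene was counted against, not that it was expressed. Only gene symbols were read, so the coverage of a list describes how genes were named. It is not a finding about the tumor cells or their stages.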

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

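The alternatives listed before the data were examined (scaling, library total, low-count filter, prior count, depth, fold threshold, counting interval, list summary and removal of other cell types) all need expression values by stage, so none was run. The alternatives given here were chosen after seeing the data. The number of value columns assigned to a sample by name was 0 under all 3 ways of matching tried: any label holding the name, a whole label equal to it, and titles and descriptions only. The whole-label way and the way by titles and descriptions are narrower than the first. Once the first gave 0 they could only give 0, so they add no support. The number of gene symbols found in an annotation was 36174 for GENCODE M21, 27562 for RefSeq GRCm38.p6 and 36225 for either. The number of list symbols with a row was 1366 with letter case kept or ignored.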
